A study of Mus musculus with 22 samples.

How the data were processed

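Poly(A) RNA from mouse trophoblast stem cells was sequenced in 6 libraries, 3 of unmodified cells and 3 of cells with Klf5 knockdown. Groups and replicate numbers were taken from the sample titles. The 16 chromatin samples of the series (ATAC, ChIP and input) were not analysed here, since no processed values of them were used.

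The authors deposited a file of whole-number counts per gene for each library. Per the file headers it gives the gene's identifier, chromosome, start, end, strand, exonic length and the library's count. The submitters' processing notes name STAR, StringTie and limma without roles, and the genome build mm10. They also name Bowtie2 version 4.4.7 (as written there), SAMtools 1.11, Picard 2.6.0, MACS2 2.2.6, ChIPseeker 1.22.1 and bedtools, again without roles. The program that counted the reads and whether it used strand are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and near-identical copies (prolactin, Psg, cathepsin and Rhox genes) are uncertain. Totals were between 6369936 and 9627091 counts per library. Mitochondrial transcripts took between 1.57% and 1.86% of the counts, and the most abundant gene, Eef1a1, less than 1% in each library. Replicate pairs differed, by a chi-square comparison over genes with at least 10 counts in a pair, by 1.45 to 5.45 per degree of freedom. Sampling noise gives 1, so no library was treated as a duplicate. The highest values, 5.45 and 5.37, were the pairs that hold replicate 2 of the unmodified cells.

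The authors also deposited a table of FPKM values for the same 6 libraries, normalized by them to gene length and library depth. It had 68066 rows, and 116 gene names stood on more than 1 row. Of these, 106 stood on exactly 64 rows each, the number that results when 2 loci of a name are joined in every combination over 6 libraries. For 41 of the 116 names the rows held every combination of the name's distinct values. The 116 names, on 12891 rows, were left out, and 55175 names were used, as an alternative to the counts only.

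Gene symbols were joined by Ensembl identifier. Of 55401 identifiers 55141 had a symbol, 54349 of them at the same version, and 260 had none. The reading and joining were done in Python 3.11.15 with pandas 2.3.3.

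Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes were kept by filterByExpr by group, which left 14610, scaled by TMM, and tested with the robust quasi-likelihood F test of knockdown against unmodified cells with no covariate. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. CPM values use the TMM library sizes. The SE of a log2 fold change is its absolute value over the square root of F. The common biological coefficient of variation was 0.0682.

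The test, 20 gene lists holding 408 genes and the rule for named genes were fixed before the data were examined. Named were Klf5, 7 trophoblast stem cell factors, the 6 highest and 6 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM and no overlap between groups (predicted genes left out), and up to 3 members of each list with the smallest adjusted p. Lists were compared with the other genes by camera with a preset correlation of 0.01, two-sided, adjusted over the 20 lists. Camera with an estimated correlation was run beside it, as was fry, which tests a list's own genes and does not compare them with others. Adjusted over the list alone, 1 more gene rose in each of the trophoblast stem cell regulator (7 higher), interferon (9), glycolysis and hypoxia (14) and imprinted (11) lists, and the counts of the other lists were those given. Where a group had no count, a bound was computed with a floor of 3 counts over the group. Ratios with 1 count in a group have an exact 95% binomial interval.

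The procedure was tested on simulated counts for this comparison, with 14434 genes and 200 of them changed. edgeR called 54.5% of genes changed by 0.5 on the log2 scale, 88.1% of those changed by 1 and 95.5% of those changed by 2, and 0.133% of the unchanged genes. In a simulated set of lists the changed list was called and 0 of 19 unchanged lists were. The simulated genes varied independently, so the preset correlation was not tested by this. Only 200 genes were changed in the simulation, against 58.8% of the tested genes called in the data, so its rates need not hold for the data.

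Alternatives planned before the data were examined were DESeq2 size factors, upper-quartile scaling, library totals, no filter beyond 1 count, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, a replicate block, each replicate left out in turn, limma with trend on log2(FPKM + 1) for genes with a mean FPKM of at least 0.5, a pseudocount of 0.1, no FPKM filter, and glmTreat against a 1.5-fold change. Fold changes on the log2(FPKM + pseudocount) scale understate the change of low genes. Figures were drawn with matplotlib 3.10.9.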

Results

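Gene expression was measured by sequencing of poly(A) RNA from mouse trophoblast stem cells, the self-renewing cells that give rise to the trophoblast lineages of the placenta. The 6 RNA libraries formed 2 groups of 3, unmodified cells and cells in which Klf5 had been knocked down. Klf5 is a zinc-finger transcription factor of the Krüppel-like family. The cells were kept on mouse embryonic fibroblasts whose division had been blocked with mitomycin C, so RNA from these feeder cells could be present in a library. The labels do not say how the knockdown was made, nor whether the replicates were separate cultures. The p-values therefore measure the spread between these samples, which may be technical. The deposited count files held between 6369936 and 9627091 counts per library over 55401 genes. Of the 22 samples in the series, 16 were chromatin samples (4 of ATAC and 12 of ChIP or input) and were not analysed here.

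The comparison of knockdown with unmodified cells bears on the role of Klf5 in trophoblast stem cells, which the series set out to examine. No RNA library was labelled as a control for the knockdown procedure. Effects of the procedure therefore cannot be told apart from effects of lower Klf5. Klf5 itself (ENSMUSG00000005148.8, mm10 chromosome 14, start 99298691, end 99315036, plus strand) was lower in all 3 knockdown libraries. Its level was 108 ± 11.5 CPM (counts scaled to a common library size, mean ± SD, n = 3) in unmodified cells and 21.3 ± 1.54 CPM in knockdown cells. This is a 5.08-fold decrease, with a log2 fold change of -2.35 ± 0.10 (SE) and an edgeR quasi-likelihood adjusted p = 3.57e-12. The unmodified libraries held 104.9, 98.6 and 120.8 CPM of Klf5 and the knockdown libraries 20.4, 23.1 and 20.5 CPM.

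Most of the core transcription factors of trophoblast stem cells fell with Klf5. Esrrb, an orphan nuclear receptor, fell 297-fold, from 509 ± 20.3 to 1.70 ± 0.23 CPM (mean ± SD, n = 3). Sox2 fell 52.7-fold, from 146 ± 21.7 to 2.86 ± 0.77 CPM, and the T-box factor Eomes fell 18.1-fold, from 276 ± 6.30 to 15.2 ± 0.35 CPM. The homeobox factor Cdx2 fell 9.44-fold, Elf5 5.20-fold and Tead4 3.26-fold. In the files' coordinates (mm10) Esrrb lies on chromosome 12 from 86361117 to 86521628, Eomes on chromosome 9 from 118478212 to 118486132, Cdx2 on chromosome 5 from 147300805 to 147307270 and Sox2 on chromosome 3 from 34650405 to 34652461. Tfap2c went the other way, from 217 ± 14.8 to 415 ± 6.65 CPM, a log2 fold change of 0.93 ± 0.06 (SE). The weakest of these 7 tests was that of Cdx2, with an edgeR adjusted p = 1.01e-08. Of the 19 tested members of a list of trophoblast stem cell regulators, 11 fell, 6 rose and 2 did not pass, with a median log2 fold change of -1.58. The list stood below the other genes with a camera adjusted p = 1.45e-09, and with adjusted p = 0.0217 with an estimated correlation. Markers of feeder cells, with a median of -3.30, and the summed Y-linked genes, at -2.02, were lower in the same libraries.

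**Figure D1:**
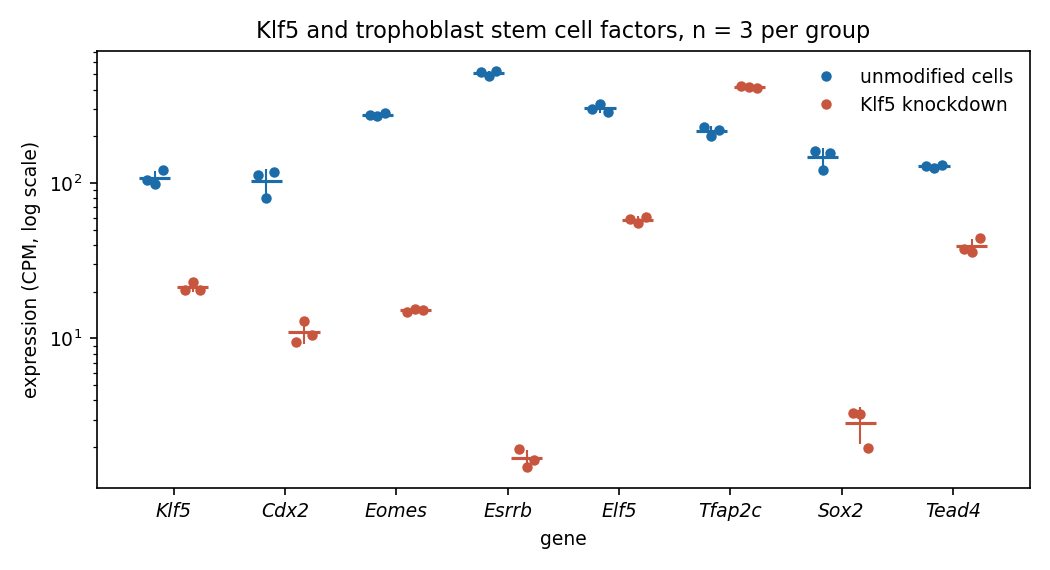
Expression of Klf5 and 7 trophoblast stem cell factors in CPM on a log axis. Each point is a library, horizontal bars are group means and vertical bars are SDs (n = 3 per group). In every gene the groups are separate, and Tfap2c alone is higher in the knockdown.

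Of the 20 lists, the lowest median was that of genes that respond to fibroblast growth factor (FGF) and ERK kinase signalling. All 16 listed members were tested and all 16 fell, with a median log2 fold change of -4.11 and a range from -9.48 to -0.68. Cyclin D1 (Ccnd1) fell 48.0-fold, from 638 ± 18.2 to 13.3 ± 1.36 CPM (mean ± SD, n = 3). The ERK phosphatase Dusp6 fell from 173 ± 7.29 to 0.42 ± 0.36 CPM, and Spred2, an inhibitor of the pathway, fell 16.7-fold, from 246 ± 5.31 to 14.6 ± 0.71 CPM. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, fell from 132 ± 6.01 to 0.14 ± 0.24 CPM, with 4 counts left over the 3 knockdown libraries. The list had a camera adjusted p = 4.77e-52, and adjusted p = 0.0217 with an estimated correlation, which was 0.48. Markers of fibroblast feeder cells fell in the same libraries, with a median log2 fold change of -3.30. The culture medium of trophoblast stem cells contains Fgf4, and the labels also describe a medium without it; which medium each RNA library came from is not stated.

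Among the genes of differentiated trophoblast, most of the tested markers of the junctional zone and of the labyrinth were higher. Of 21 listed spongiotrophoblast and glycogen cell genes, 13 had too few counts to be tested, 5 rose and 3 fell. The 3 that fell were Pcdh12 (2.75-fold), Aldh1a3 (2.10-fold) and Flt1 (1.39-fold). Ascl2 (chromosome 7, 142966829 to 142969264), a basic helix-loop-helix factor required for spongiotrophoblast, rose 54.2-fold, from 0.91 ± 0.13 to 49.8 ± 2.49 CPM (mean ± SD, n = 3). Phlda2 (chromosome 7, 143501545 to 143503150), an imprinted gene that restrains placental growth, rose 28.9-fold, from 23.3 ± 4.74 to 682 ± 13.2 CPM, and Plac1 rose 7.39-fold. The list median was 1.11, with a camera adjusted p = 4.14e-07 and adjusted p = 0.0217 with an estimated correlation. The call was lost with the deposited FPKM values in place of the counts (camera adjusted p = 0.0965), and over 17 alternatives the adjusted p ran from 6.24e-09 to 0.175. Of 15 tested syncytiotrophoblast and labyrinth genes, 12 rose, 1 fell and 2 did not pass, with a median of 1.10. Dlx3, a homeobox factor of the labyrinth, rose from 1.22 ± 0.14 to 22.7 ± 1.74 CPM and the lactate transporter Slc16a3 rose 2.46-fold, while Ly6e fell 2.28-fold. This list had a camera adjusted p = 0.00148, and adjusted p = 0.0612 with an estimated correlation.

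The tested part of the giant cell list went down. Of its 21 members 12 had too few counts to be tested, and of the other 9, 6 fell, 1 rose and 2 did not pass, with a median log2 fold change of -1.62. Timp1, an inhibitor of metalloproteinases, fell 26.2-fold, from 457 ± 4.25 to 17.4 ± 0.45 CPM (mean ± SD, n = 3). Pparg, a nuclear receptor with a role in labyrinth differentiation, rose 6.70-fold, from 2.32 ± 0.22 to 15.8 ± 1.61 CPM. The prolactin-family gene Prl2c3 fell 3.89-fold, a value that is uncertain because near-identical copies of the gene can share reads. The list had a camera adjusted p = 0.00313, and adjusted p = 0.0815 with an estimated correlation. Feeder markers fell in the same libraries, with a median of -3.30. The call was lost with limma-voom (camera adjusted p = 0.0513), and the adjusted p ran from 0.00194 to 0.0903 over 17 alternatives.

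Fibroblast feeder markers fell without exception. All 22 tested members were lower, with a median log2 fold change of -3.30 and a range from -6.80 to -1.46. The collagen gene Col1a2 fell 10.5-fold, from 683 ± 44.6 to 65.4 ± 2.06 CPM (mean ± SD, n = 3), Col6a3 fell from 289 ± 17.5 to 13.7 ± 0.60 CPM and the cadherin Cdh11 fell 22.5-fold. The list had a camera adjusted p = 2.60e-61, and adjusted p = 0.00667 with an estimated correlation. The summed counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty fell 4.06-fold, from 36.5 ± 4.58 to 9.00 ± 1.18 CPM. Xist, the RNA that coats the inactive X chromosome of female cells, stood at 626 ± 130 CPM in unmodified and 1112 ± 22.1 CPM in knockdown cells, with an edgeR adjusted p = 0.00273.

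Most of the tested mesenchymal genes fell and most of the tested epithelial genes rose. In the mesenchymal transition list 19 of 20 tested genes fell and 1 rose, with a median of -2.43. Fibronectin (Fn1) fell 16.4-fold, from 3367 ± 158 to 205 ± 9.70 CPM (mean ± SD, n = 3), the plasminogen activator inhibitor Serpine1 fell 8.35-fold and the actin-binding protein gene Tagln fell 10.1-fold. The list had a camera adjusted p = 3.33e-41, and adjusted p = 0.00667 with an estimated correlation. These genes fell in the libraries in which the feeder markers and the Y-linked sum were lower. In the epithelial junction and keratin list 17 of 23 tested genes rose, 3 fell and 3 did not pass, with a median of 1.08. Keratin 18 (Krt18) rose from 549 ± 36.5 to 1590 ± 19.3 CPM, the desmosomal gene Pkp2 rose 3.31-fold and the tight junction gene Cldn6 rose 2.61-fold. For this list the camera adjusted p was 1.57e-09, and adjusted p = 0.0489 with an estimated correlation.

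Tested genes of the pluripotent embryo mostly fell, and markers of blood, vessels and primitive endoderm did not pass as lists. Of 9 tested embryonic pluripotency genes (19 listed) 7 fell and 2 rose, with a median of -1.62. Sox2 had the smallest adjusted p of this list, and Dppa4 and Dppa2 fell 3.95-fold and 3.81-fold. Camera gave the list an adjusted p = 0.000522, and adjusted p = 0.14 with an estimated correlation. Of 7 tested blood and endothelial genes (17 listed) 4 fell, 1 rose and 2 did not pass, and the list did not pass (camera adjusted p = 0.0671, and adjusted p = 0.331 with an estimated correlation). Its camera adjusted p was 0.0389 without the filter on low counts, 0.0356 without replicate 1 of the knockdown and 0.0332 with the FPKM values, and ran from 0.00558 to 0.361 over 17 alternatives. The VEGF receptor gene Kdr fell 6.76-fold, Pecam1 fell 2.33-fold, and the macrophage lysozyme gene Lyz2 had no knockdown count, at least 72.1-fold lower with the floor at 3 counts over the group. Feeder markers fell in the same libraries, by the median given above. Of 6 tested primitive endoderm genes (15 listed) 3 fell, 2 rose and 1 did not pass (camera adjusted p = 0.59). Dab2 fell 3.63-fold and Foxq1, with 4 knockdown counts, fell from 2.80 ± 1.02 to 0.18 ± 0.09 CPM, while the collagen gene Col4a1 rose 1.30-fold.

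Other members of the Klf and Sp family moved in both directions. Of 19 tested, 7 rose, 7 fell and 5 did not pass (camera adjusted p = 0.40). Klf6 rose from 179 ± 10.9 to 390 ± 11.8 CPM (mean ± SD, n = 3) and Klf11 rose 2.70-fold, while Sp4 fell 3.18-fold. The genes for histone acetyltransferases, deacetylases and their readers likewise split, with 7 of 26 tested higher, 8 lower and 11 not passing (camera adjusted p = 0.59), a median of 0.01 and a mean of -0.01. The deacetylase gene Hdac7 fell 6.24-fold, from 79.4 ± 7.76 to 12.6 ± 1.41 CPM. Hdac6 rose 1.72-fold and the coactivator gene Ncoa2 rose 2.36-fold.

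Proliferation and growth-arrest genes changed in both directions and did not pass as lists. In the cell cycle list 6 of 23 genes rose, 7 fell and 10 did not pass (camera adjusted p = 0.92), with a median of 0.02 and a mean of -0.02. Rrm2, a subunit of ribonucleotide reductase, fell 2.40-fold, and the proliferation antigen gene Mki67 rose from 218 ± 23.0 to 438 ± 17.5 CPM (mean ± SD, n = 3), with Ccnb2 1.39-fold higher. Of 20 p53 targets and cell cycle inhibitors 6 rose, 10 fell and 4 did not pass (camera adjusted p = 0.81), with a median of -0.13 and a mean of 0.01. Cdkn1a fell 2.32-fold and Perp 1.66-fold, whereas the imprinted inhibitor Cdkn1c rose 5.51-fold, from 47.9 ± 9.39 to 265 ± 2.13 CPM.

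Of the interferon, glycolysis, cholesterol and stress lists, the first 2 passed camera with the preset correlation and none with an estimated one. Of 13 tested interferon response genes 8 rose, 1 fell and 4 did not pass, with a median of 0.84. The chemokine gene Cxcl10 rose from 0.57 ± 0.30 to 18.97 ± 0.19 CPM (mean ± SD, n = 3), Irf7 rose 4.90-fold and the RNA sensor Ddx58 rose 1.77-fold. The interferon list had a camera adjusted p = 0.00563, and adjusted p = 0.14 with an estimated correlation. Of 23 glycolysis and hypoxia genes 13 rose, 6 fell and 4 did not pass, with a median of 0.28. Ndrg1 rose 6.21-fold, Bnip3 4.49-fold and the glucose transporter gene Slc2a3 4.09-fold, the last from 228 ± 11.6 to 932 ± 14.7 CPM. For these genes the camera adjusted p was 0.00341, and adjusted p = 0.14 with an estimated correlation. It was 0.167 with the FPKM values and ran from 1.21e-05 to 0.179 over 17 alternatives. Cholesterol synthesis genes did not pass as a list, with 10 of 20 higher, 4 lower and 6 not passing (camera adjusted p = 0.163), among them Ldlr at 1.95-fold, Stard4 at 1.63-fold and Hmgcs1 at 1.40-fold higher. The integrated and unfolded protein stress list had 6 of 20 higher, 8 lower and 6 not passing (camera adjusted p = 0.695, direction up, against a median of -0.10), with Atf3 3.89-fold and Trib3 2.21-fold higher and Phgdh 1.88-fold lower.

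Imprinted genes changed by large amounts in both directions. Of 21 tested, 10 rose, 7 fell and 4 did not pass, with a median log2 fold change of 0.13 and a range from -4.49 to 5.76. Ascl2 and Phlda2, the genes of this list that rose most, are also those that rose most in the spongiotrophoblast list. Cdkn1c is shared with the list of p53 targets and cell cycle inhibitors. The results of these lists are therefore not separate. Peg10, a retrotransposon-derived gene needed for placental development, rose from 736 ± 65.1 to 3962 ± 51.8 CPM (mean ± SD, n = 3), a 5.39-fold change. Mest fell 6.29-fold, from 335 ± 15.5 to 53.2 ± 2.60 CPM, and the long noncoding RNA H19 fell 22.5-fold, from 74.9 ± 2.04 to 3.33 ± 0.25 CPM, beside the fall of the feeder markers. The list had a camera adjusted p = 0.00486, and adjusted p = 0.0756 with an estimated correlation. The call was lost with limma-voom (0.166) and with the FPKM values (0.55), and the adjusted p ran from 8.99e-07 to 0.593 over 17 alternatives.

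Genes were also named by the size of their change. The 6 with the lowest fitted log2 fold change were Mmp3, Mmp10, Egr3, Mcpt8, Spry4 and Sox3. The metalloproteinase gene Mmp3 had 3049 counts in unmodified and 1 in knockdown libraries, 3251 times lower with a 95% counting interval from 583 to 128449. Mmp10 had 1187 and 1, 1266 times lower with an interval from 227 to 50032. No knockdown count was seen for the early growth response gene Egr3, the mast cell protease gene Mcpt8 or Sox3. With the floor at 3 counts over the group these were at least 114-fold, at least 107-fold and at least 81.7-fold lower, bounds that Esrrb (297-fold) exceeds, so their rank rests on fitted values. The 6 with the highest log2 fold change were Ascl2, Cxcl10, Phlda2, Chdh, Dpf3 and Gata2. Gata2, a transcription factor of trophoblast, rose 18.5-fold from 16.6 ± 1.73 to 306 ± 1.25 CPM (mean ± SD, n = 3). The choline dehydrogenase gene Chdh rose 20.2-fold from 1.62 ± 0.70 to 34.1 ± 3.52 CPM, and Dpf3, a chromatin remodelling subunit, rose from 0.56 ± 0.12 to 10.8 ± 1.504 CPM. Intervals and floors cover counting error only.

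**Figure D2:**
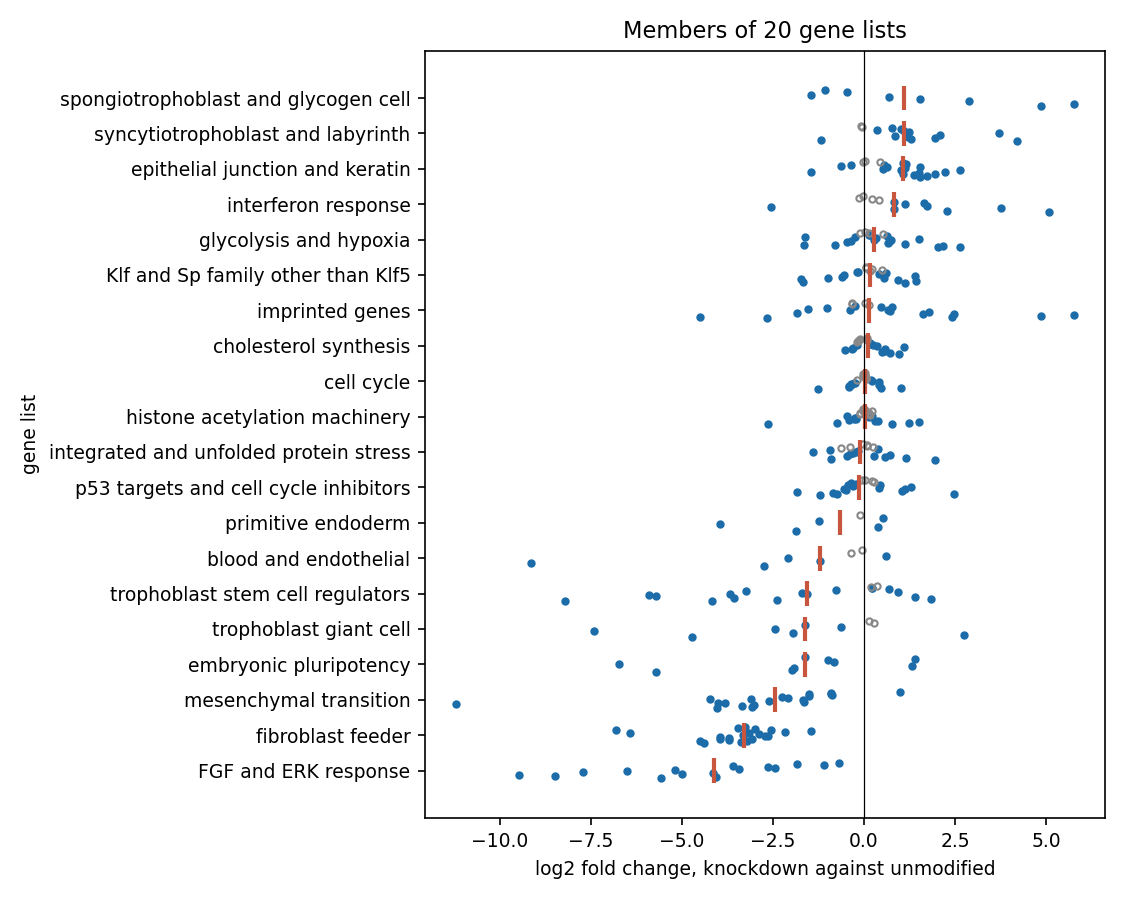
Log2 fold changes of the tested members of 20 gene lists, knockdown against unmodified cells, ordered by list median. Filled points passed the edgeR test at an adjusted p of 0.05, open points did not, and the red bars are list medians, from -4.11 for the FGF and ERK response genes to 1.11 for the spongiotrophoblast and glycogen cell genes. Genes with no knockdown count, such as Lyz2, are drawn at their fitted value, which is not a measured fold.

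Over all genes, 8588 of 14610 tested (58.8%) passed the edgeR threshold, 4177 higher and 4411 lower in the knockdown. Which side held more turned with the setting, to 4509 higher and 4144 lower with upper-quartile scaling, 4961 and 3835 with library totals, 3620 and 3616 for genes with a mean of at least 5 CPM, and 4374 and 3402 with the FPKM values at a pseudocount of 1 (4305 and 3353 at 0.1, and 3980 and 3550 without a filter). More than 2-fold changes numbered 2902, of which 1022 were higher and 1880 (64.8%) lower. Beyond 8-fold, 553 genes were lower and 56 higher. The libraries of the 2 groups did not overlap in CPM for 9384 genes (64.2%), against 10% expected by chance for 3 against 3. The main axis of a principal component analysis held 89.2% of the variance and separated the groups. The count of more than 2-fold changes was 1819 when only genes with a mean of at least 5 CPM were tested, and 1810 with the FPKM values at a pseudocount of 1.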

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

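The direction of Klf5 and of every other of the 73 named genes, and their side of the threshold, held under each alternative that gave a value, all of them planned. The number of changed genes ran from 7236 (mean of at least 5 CPM, 11848 genes tested) to 9555 (no filter, 26838 tested), beside 8588. Leaving out each replicate in turn gave 7709 to 9542 changed genes, the highest without replicate 2 of the unmodified cells, and a Klf5 log2 fold change between -2.40 and -2.26. DESeq2 called 7581 genes, of which 7121 were among the 8588. With library totals, 43.6% of the calls were lower, against 51.4% with TMM. More than 2-fold changes numbered 1819 with the stricter filter, which tests fewer genes, and 1810 or 1805 with FPKM at a pseudocount of 1, with and without a filter, against 2713 at a pseudocount of 0.1; a larger pseudocount shrinks folds of low genes by construction. A replicate block gave 8271 changed genes. Same-numbered libraries had correlations of -0.053, -0.030 and -0.008 in their deviations from the group means. No library correlated best with its own number, so no pairing by number was seen, though so few libraries cannot exclude it. Lists past the threshold numbered 12, but 6 with an estimated correlation, 18 with fry's directional test and 20 with its mixed test, which is passed by lists whose genes move either way. The syncytiotrophoblast and imprinted lists lost the call with estimated correlations of -0.02 and -0.04, below the preset of 0.01. A higher correlation between genes is therefore not what took their calls. The other lists that lost it had estimated correlations above the preset, which need not be what took their calls. The unadjusted camera p of the spongiotrophoblast list, with an estimate of -0.10, also rose, from 1.24e-07 to 0.00543. That of the stem cell regulator list, with an estimate of 0.016, rose from 2.90e-10 to 0.00377. What else differs between the 2 forms of the test was not examined. The direction of the cell cycle list turned with DESeq2 (adjusted p = 0.821), limma-voom (0.96), without replicate 2 of the unmodified cells (0.989) and with fry (0.00492), and that of the stress list with limma-voom (0.969) and without that replicate (0.996); the cause was not tested. With each replicate left out in turn these adjusted p ran from 0.814 to 0.989 and from 0.617 to 0.996. At these depths the chosen floor of 3 counts over a group stands at 0.127 CPM in the knockdown and 0.136 CPM in the unmodified cells.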

Other observations

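The tests of composition scaling, of the culture medium and of the size of the feeder loss were chosen only after the result was seen, as were the domain and the gene families described here. On distal chromosome 7, several imprinted genes named in the report lie within 1 Mb of each other and moved in different directions. From H19 (start 142575529) the order ran through Igf2, Ascl2 (start 142966829), Cd81, Tssc4, Kcnq1ot1, Cdkn1c (start 143458339), Slc22a18 and Phlda2 (start 143501545) to Nap1l4 (end 143549106). Ascl2 rose by 5.76 ± 0.17 (log2 fold change ± SE), Phlda2 by 4.85 ± 0.10, Cdkn1c by 2.46 ± 0.10 and Slc22a18 by 2.02 ± 0.22. Between them, Kcnq1ot1, the noncoding RNA of the same domain, had a log2 fold change of 0.21 ± 0.25 (edgeR adjusted p = 0.496), Tssc4 rose by 0.44 and Cd81 fell by 0.53. H19 fell by 4.49 ± 0.12 while its neighbour Igf2 rose by 0.46 ± 0.08, and Nap1l4, past Phlda2, had a log2 fold change of -0.15 ± 0.06 (edgeR adjusted p = 0.0328). Igf2 overlaps its antisense gene Igf2os, and the reads of these cannot be told apart.

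Gene families grouped by the stem of their symbols added further groups to the list results. Of 153 families with at least 10 tested genes, 10 passed camera with the preset correlation, all lower in the knockdown, and 0 passed with an estimated correlation (adjusted p = 0.831 for each of the 10). Among 27 collagen genes, a family that shares members with the feeder list, 20 fell and 3 rose, with a median log2 fold change of -1.77 (camera adjusted p = 2.07e-16). Of 10 Sox genes 8 fell and 0 rose, with a median of -2.30 (camera adjusted p = 1.22e-05), and of 11 Tnfrsf receptor genes 9 fell (camera adjusted p = 0.00622). Of 47 genes of the large ribosomal subunit 41 fell and 0 rose, with a median of -0.32 (camera adjusted p = 0.0126), while of 46 genes of the small subunit 33 fell and 7 rose, also with a median of -0.32, and did not pass (camera adjusted p = 0.355); near-identical pseudogenes make these counts uncertain. Of 11 Hoxb genes 10 fell, with a median of -2.68, although the family missed the threshold (camera adjusted p = 0.0591). All these falls stand beside that of the feeder list (median -3.30) in the same libraries.

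The fall of the fibroblast feeder genes did not rest on the choice among 4 scalings, since the list median nearest to 0 over them was -3.22. These scalings moved the median log2 fold change of all genes only between 0.005 and 0.086. They could not have brought the list near 0, so a larger shift in scaling was not tested. None of the 4 scalings would show a change in total RNA per cell, so that is not covered. Fewer feeder cells in the knockdown libraries stay open and may account for part or all of the fall. The Y-linked genes, foreign to a line whose high Xist points to female cells, also fell, with a log2 fold change of -2.02 ± 0.15 (SE). Of the 22 feeder genes, which no other list held, 20 fell further than the Y-linked sum by more than 2 combined SE. This argues against a feeder loss of the size of the Y-linked fall as the whole fall, and not against a larger loss. The Y-linked fall need not equal the feeder loss, since how much of the Y-linked counts came from feeder cells is not known. Of the 22 feeder genes, 15 stayed above 10 CPM in the knockdown. The most abundant in unmodified cells, Col1a1 and Col1a2, went from 689 and 683 CPM to 81.5 and 65.4 CPM, and Col5a1 was the highest in the knockdown at 127 CPM. A change of these genes within the trophoblast cells, as an effect of the knockdown, is untested and also stays open.

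The fall of the FGF and ERK response genes likewise did not rest on the choice among the 4 scalings, with a list median of -4.03 at its nearest to 0. The scalings are again too alike to test a larger shift, and a change in total RNA per cell is again not covered. A feeder loss of the size of the Y-linked fall, 4.06-fold, is argued against as the whole fall, since 13 of the 16 genes fell further than the Y-linked sum by more than 2 combined SE. As a part of the fall, or with a larger loss as the whole of it, fewer feeder cells cannot be told apart from an effect in the trophoblast cells. The test planned for it, the slope of this list on the feeder list over the 3 unmodified libraries, came to -6.12, but the feeder median varied by 0.02 between those libraries, too little to read a slope. Fgf4 in the medium could differ between the groups too, as 0 of the 6 RNA libraries had a label naming its medium. The knockdown of Klf5 itself stays among the open explanations.

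The excess of falling over rising genes beyond 2-fold, 64.8% lower, held under 4 scalings at 59.7% or more. It therefore did not rest on the choice among them, and a larger shift than they span was not tested. A correction for exonic length left 67.2% lower, so the excess did not shrink from 64.8%. It moved the log2 fold changes by 0.0448 on average, below the 0.05 set beforehand for reading the test. The trend with length was thus small beside a 2-fold change. By the rule set beforehand, a correction this small cannot decide whether length was the source of the excess. The values show only that taking out the fitted trend left the excess in place. Other effects of length were not tested. Feeder genes among those that fell might add to the excess: leaving out the 1306 lower genes whose falls lay in the range of the feeder list gave 36.0% lower, an outcome that leaving out falling genes brings about by itself, so this explanation cannot be told apart. For the count of changed genes, the real grouping gave 8588 and the highest of the other groupings of the 6 libraries 0; as 1 of 10 splits gave as many, the splits are too few for a share under 0.05.

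Histone transcripts, most of which lack a poly(A) tail, took 0.0106%, 0.0073% and 0.0113% of the counts in the unmodified libraries and 0.0042%, 0.0042% and 0.0041% in the knockdown libraries. Between the FPKM table and the counts, 7 genes called in both had opposite signs, and 6681 of 8025 calls tested in both were shared. For the comparison of levels, counts were scaled to gene length and library total. Within a library the log2 values then had Pearson correlations of 0.78 to 0.80 with the FPKM values over 6884 genes. With each gene's mean over the libraries taken out, these were 0.84 to 0.92. Differences between results from the FPKM values and from the counts stand beside this mismatch.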
